A study of Mus musculus with 15 samples.

How the data were processed

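CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA next to its target, was applied to HPC-7 cells, a mouse early haematopoietic line made from embryonic stem cells. Per the labels, about 150000 cells went into each reaction, control cells were profiled for IgG, the promoter mark H3K4me3, the transcription factor YY1 and the cohesin subunit SMC3, and cells with an shRNA against YY1 (shYY1) were profiled for SMC3. Each of these 5 groups had 3 libraries that the labels' protocol calls biological replicates. The control cells are called wild type in the titles and carry the name of a luciferase shRNA in the descriptions. The descriptions name Abcam for the first SMC3 library of each arm only, while the labels' protocol names an Abcam antibody for SMC3 in general, so whether the other SMC3 libraries used the same antibody is not clear; the replicate spread and the result of leaving out those libraries may include a change of antibody. The shYY1 descriptions all carry the same number, whose meaning is not given in the sources used here. Peak lists of 12 of the 15 libraries were used; the 3 IgG libraries were not analysed here. No YY1 library of shYY1 cells was analysed here, so the extent of the knockdown was not measured.

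The deposited files are lists of called peaks, 1 list per library, with the start, the end and the offset of the summit in base pairs. They carry no score, height, q value or read count, so the sequencing depth is unknown and no interval that needs it is given. Per the submitters' processing notes, cutadapt 4.5, Bowtie2 2.5.1, Picard 3.1.1, MACS2 2.2.9.1 and the mouse build mm10 were used. Their settings, the threshold for a peak, the treatment of duplicates and any use of IgG as background are not given in the sources used here. Between 49 and 99 numbers were missing from the running peak names of each deposited list, so some called peaks had been removed before deposit. The number of called peaks depends on depth as well as on occupancy, and counts of peaks cannot separate these.

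Peaks of a target were merged over its libraries when they shared at least 1 bp, and a merged region was called reproducible when at least 2 of 3 libraries had a peak in it. Coordinates are given for mm10, counted from 1. Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes given as spans without strand. Because the strand was not given, a gene end means a position within 1000 bp of either end of the span, in place of the transcription start that had been planned, and a start inside the span is missed. A peak between 2 neighbouring genes counts for both. No genome sequence was used, so the planned search for YY1 and CTCF motifs was not run. The planned stricter peak threshold was not run either, since the lists hold no score.

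Group means were compared with an exact two-sided permutation test over the 20 assignments of 6 libraries, whose smallest possible p is 0.1, so no difference between control and shYY1 could pass 0.05. The occupancy of H3K4me3 regions with and without YY1 was expressed as a log2 odds ratio per library with 0.5 added to each cell. Overlap of YY1 and SMC3 regions was compared with 1000 random placements on the same chromosome. Gene lists were tested with Fisher's exact test against all other genes with a reproducible H3K4me3 region at an end, with Benjamini-Hochberg adjustment over the 18 lists of each target; genes and regions are not independent replicates, so these p values describe the libraries at hand. Only Ahsp of the listed genes was not found in the annotation. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named all cohesin genes and Yy1, the 4 members of each list with the highest YY1 rank, the 10 genes with the highest joint YY1 and SMC3 rank, and up to 15 genes with SMC3 in every library of one arm and none of the other. It asked for peak scores; the percentile of peak length within a library took their place. Not every gene that the rule selected is reported here.

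The alternatives were another minimum overlap of 50%, regions called in 3 of 3 libraries, leaving out each replicate, leaving out both SMC3 libraries whose description names Abcam, a replicate block, a window of 2500 bp and joining peaks within 1000 bp. The gene-list tests against genes with H3K4me3 were planned. Lists cut to equal length, the longer peaks of each list, and a variant that counts only those gene ends that themselves carry H3K4me3 were added after the data had been seen. So were 36 tests of the 18 lists among YY1 genes and among SMC3 genes. A rule that sets aside the equal-length comparison of YY1 regions when over 85% of each list lies in them was also added after its value had been seen.

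The calculations were tested on simulated data. A planted difference of -2 in the log2 odds ratio over 16653 regions was recovered as -1.90. All of 200 planted losses among 8061 regions were found. They were set as called in every control and no shYY1 library, so the rule had to find them. The largest count in the other 9 splits of that simulation was 124. Simulated libraries shared 1 mean control call rate, unlike the real lists. With no difference planted the recovered value was 0.09. Randomly placed regions gave a fold of 0.986, and 4.5% of 200 random gene lists had an unadjusted p under 0.05. No pair of libraries had an identical list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.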

Results

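The peak lists described H3K4me3, YY1 and SMC3 in control HPC-7 cells and SMC3 in shYY1 cells, with 3 libraries each. H3K4me3 lists held 17384 ± 574 peaks (SD, n = 3), YY1 lists 7639 ± 3548 and control SMC3 lists 3722 ± 1439. The shYY1 SMC3 lists held 2959 ± 298 peaks. The third libraries of YY1 and of control SMC3 had the fewest peaks of their groups, 3750 and 2061. Median peak length was 751 ± 77.5 bp for H3K4me3, 333 ± 27.6 bp for YY1, 247 ± 2.65 bp for control SMC3 and 242 ± 13.1 bp for shYY1 SMC3.

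**Figure D1:**
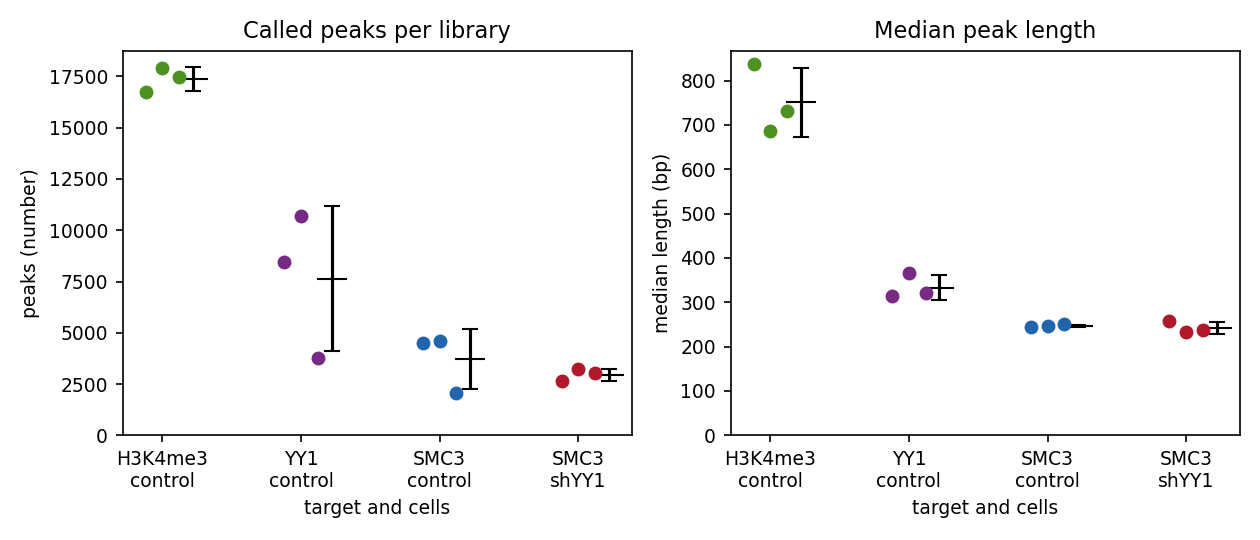
Number of called peaks (left) and median peak length in bp (right) for each library, by target and cells. Points are the 3 libraries, and the bar beside them is the mean with the SD; control SMC3 spans 2061 to 4595 peaks and shYY1 SMC3 2631 to 3213.

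The first question was where YY1 and the cohesin subunit SMC3 lie in control cells relative to H3K4me3, a mark of active promoters. Called SMC3 regions lay almost entirely on regions called for YY1 and H3K4me3. Of 3627 reproducible control SMC3 regions, 94.4% overlapped an H3K4me3 region and 94.7% a YY1 region. IgG was not analysed and motifs were not searched. Binding therefore cannot be told apart from an open-promoter background common to the YY1 and SMC3 antibodies. YY1 regions numbered 7814, of which 94.8% overlapped H3K4me3 and 43.7% overlapped SMC3. Among H3K4me3 regions with YY1, 3289 of 7268 (45.3%) had SMC3, against 99 of 9385 (1.05%) without YY1, a log2 odds ratio of 6.27. Near gene ends lay 67.4% ± 1.2 of control SMC3 peaks and 65.8% ± 5.3 of YY1 peaks (SD, n = 3), a difference of -1.58 percentage points (exact permutation p = 0.8). Random placement put 3.38% ± 0.414 of control SMC3 peaks there.

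The overlap of YY1 with SMC3 was 343-fold above random placement (0.127% of YY1 regions), with a permutation p of 0.001, the smallest that 1000 placements can give. The placements covered whole chromosomes, whereas 94.8% of YY1 and 94.4% of control SMC3 regions overlapped H3K4me3. A fold far above 1 and this p follow from that shared location alone, unlike the comparison within H3K4me3 regions above. The fold was 563 with regions called in 3 of 3 libraries. YY1 regions called in more libraries carried SMC3 more often: 3.70% of those in 1 library, 24.3% of those in 2 and 66.8% of those in 3. Only 62 control SMC3 regions had no YY1 peak in any library. Another 163, counted separately, had no H3K4me3 peak in any library, and 8 of these were at a gene end.

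Smc3 and Yy1 themselves were among the genes with all targets at an end. At Smc3, which encodes the SMC3 subunit of the cohesin ring (chromosome 19, 53600396 to 53645831), a YY1 region at 53599973 to 53600611 covered the lower end of the gene span. Control SMC3 lay at 53599921 to 53600355 and shYY1 SMC3 at 53599958 to 53600355, and each was called in 3 of 3 libraries. At Yy1 (chromosome 12, 108792945 to 108820148) the YY1 region spanned 108792739 to 108793187, the control SMC3 region 108792739 to 108793082 and the shYY1 SMC3 region 108792761 to 108793082, again in 3 of 3 libraries for each target. The presence of a peak gives no occupancy level, so an equal number of libraries does not show equal binding.

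**Figure D2:**
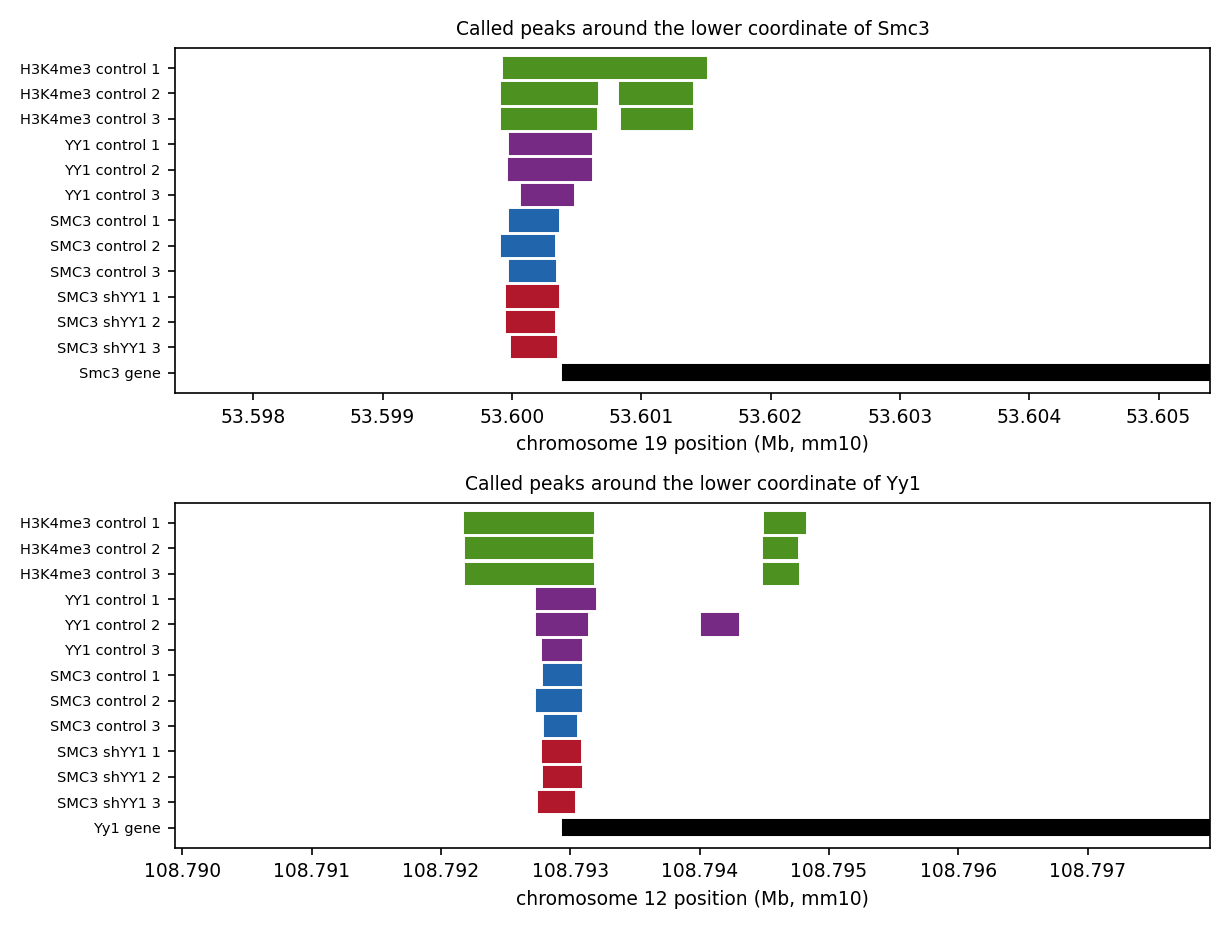
Called peaks of each library around the lower coordinate of Smc3 (chromosome 19) and Yy1 (chromosome 12), with position in Mb of mm10. Bars are peaks to scale, 1 row per library, and the black bar is the start of the gene span; every YY1 and SMC3 library has a peak at both loci.

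Smc3 was the only cohesin-list gene with reproducible H3K4me3, YY1 and SMC3 of both arms at an end. Of the 12 cohesin-list genes with H3K4me3 at an end, 9 had YY1, 3 had control SMC3 (Smc3, Smc1a and Pds5b) and 1, Smc3, had shYY1 SMC3. Smc1a, which encodes the partner of SMC3 in the ring, had SMC3 in 2 control and 0 shYY1 libraries, and Pds5b, a regulator of cohesin release, in 2 and 1. Mau2 of the cohesin loader, Stag2, Esco1, Esco2, Cdca5 and Ctcf had reproducible YY1 and no reproducible SMC3. Hdac8, Pds5a and Wapl had H3K4me3 without reproducible YY1 at an end, although Wapl had YY1 in 3 libraries inside its span. Rad21, Nipbl, Stag1 and Sgo1 had no H3K4me3 within 1000 bp of either end of the span, but each had it inside the span in 3 of 3 libraries. At Rad21 and Sgo1 it lay 1458 and 1218 bp from an end. Within their spans, Stag1 and Sgo1 had YY1, control SMC3 and shYY1 SMC3 in 3 of 3 libraries. Rad21 had YY1 in 2, control SMC3 in 2 and shYY1 SMC3 in 0 libraries. Counted over whole spans, 14 of 16 cohesin genes had YY1 in at least 2 libraries, 6 had control SMC3 and 3 had shYY1 SMC3.

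The next comparison asked which gene groups carried YY1 and SMC3 among the 10123 genes with H3K4me3 at an end. YY1 was found at 61.0% of them, control SMC3 at 29.6% and shYY1 SMC3 at 22.5%. YY1 was over-represented at genes for cytoplasmic ribosomal proteins (60 of 74, log2 odds ratio 1.42, Fisher's exact adjusted p = 0.0050), mitochondrial ribosomal proteins (57 of 72, 1.25, adjusted p = 0.013) and core splicing factors (45 of 56, 1.34, adjusted p = 0.014). Rps25, Rpl30, Rpl13a and Rpl3 ranked highest by YY1 peak length among the ribosomal protein genes, and Srsf2, Srsf3 and Srsf7 were among the highest of the splicing genes. The calls depended on the libraries and the window. With 1 YY1 library left out, a region had to be called in every remaining YY1 library, which is a stricter rule. Without YY1 replicate 1 the adjusted p was 0.45 for ribosomal proteins, 0.47 for mitochondrial ribosomal proteins and 0.47 for splicing factors; without replicate 2 it was 0.31, 0.61 and 0.57. With regions in 3 of 3 libraries it was 0.30, 0.47 and 0.47, and with a window of 2500 bp the call for mitochondrial ribosomal proteins was lost (log2 odds ratio 0.92, Fisher's exact adjusted p = 0.0558).

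No list passed the adjusted threshold for control or shYY1 SMC3, and 0 lists had an unadjusted Fisher p under 0.05 for either. Glycolytic genes had control SMC3 at 7 of 13 and shYY1 SMC3 at 4, with YY1 at 11; Eno1 and Pgk1 had SMC3 in 3 of 3 libraries of both arms. Haematopoietic stem and progenitor regulators had YY1 at 13 of 26, control SMC3 at 11 and shYY1 SMC3 at 8. Among them Zfp36l2 and Zfpm1 had SMC3 in every library of both arms, while Tal1, a master regulator of blood formation, and Etv6 had it in 3 control libraries and 1 shYY1 library. Ribosomal protein genes had control SMC3 at 27 of 74 and shYY1 SMC3 at 13, mitochondrial ribosomal genes at 14 of 72 in both, and splicing genes at 18 of 56 and 11. Genes of the electron transport chain and ATP synthase had YY1 at 57 of 78, control SMC3 at 22 and shYY1 SMC3 at 13, and proteasome genes had 26 of 37, 8 and 5. For genes against reactive oxygen species these counts were 12 of 18, 7 and 7, with Nfe2l2, Txn1 and Sod2 called in every library. DNA replication genes had 22 of 29, 11 and 7, and Pcna carried SMC3 in 3 of 3 libraries of both arms. Polycomb genes had 14 of 24, 8 and 7, and YY1 with its INO80 and Polycomb partners 13 of 17, 6 and 4.

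The lineage lists had few members with H3K4me3 at an end: 4 of 12 erythroid, 5 of 14 granulocyte and monocyte, 4 of 10 megakaryocyte and mast cell, and 4 of 14 lymphocyte genes. None of these lists passed the adjusted threshold for YY1 or SMC3. Erythroid genes had YY1 at 3 of 4 (Klf1, Tfrc and Epor) and SMC3 only at Tfrc in either arm, although Klf1 had SMC3 within 2500 bp in 3 of 3 libraries of both arms. Megakaryocyte and mast cell genes had YY1 at 2 of 4, control SMC3 at 2 and shYY1 SMC3 at 1 (Itga2b, in 2 libraries). Granulocyte and monocyte genes had YY1 at 2 of 5 (Mpo and Cebpa), and lymphocyte genes at 1 of 4 (Cd3d), with SMC3 at 0 in both lists. None of the 10 pluripotency genes or 16 liver, neural, muscle, endocrine and epithelial genes had H3K4me3 at an end, so these lists gave no test.

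**Figure D3:**
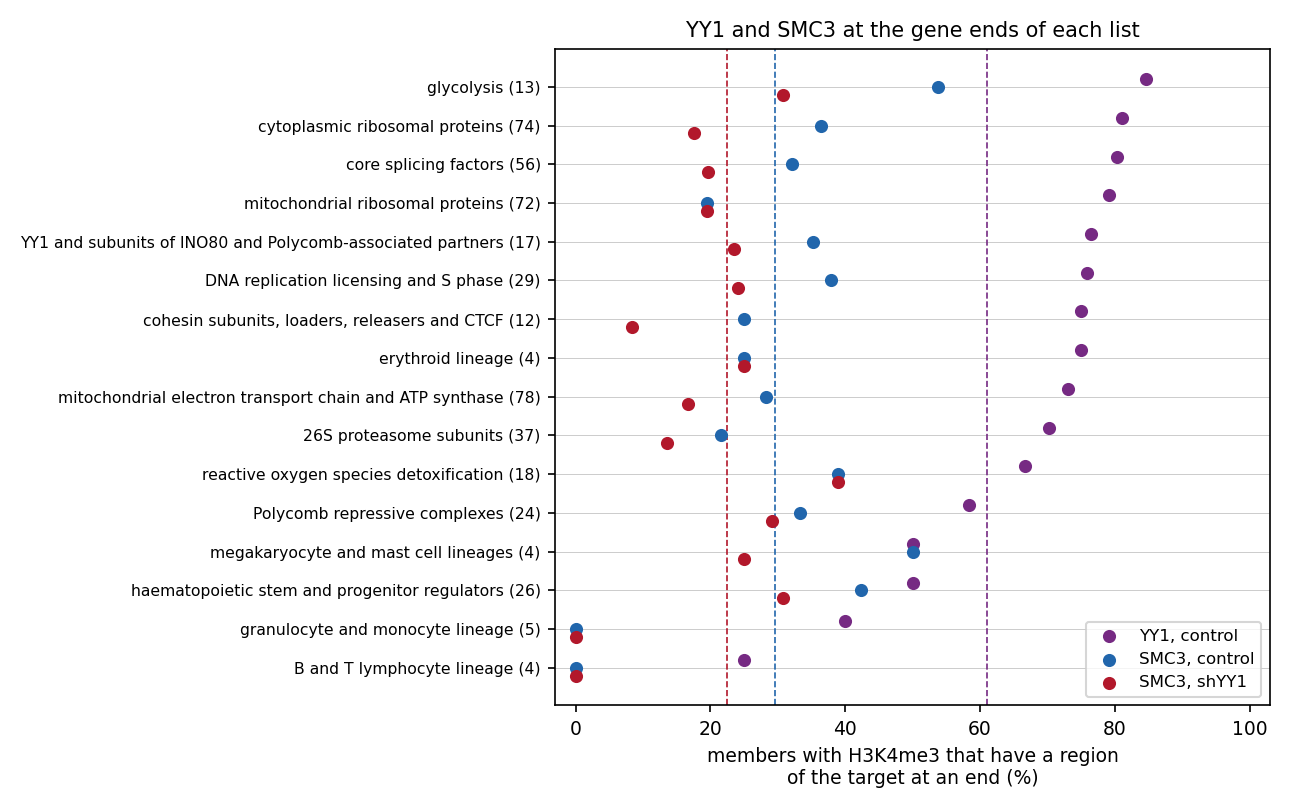
Share of the members of each gene list with H3K4me3 (number in brackets) that had a reproducible YY1, control SMC3 or shYY1 SMC3 region at a gene end, in percent. Dashed lines mark the median share of genes outside each list, near 61.0, 29.6 and 22.5%; lists without any H3K4me3 member are left out.

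The genes with the longest YY1 and SMC3 peaks together were Lnpep, Zfp36l2, Rbm15, Gsk3b, Agpat1, Rnf5, Klf13, Gm20783, LOC108167694 and Dcaf6. Lnpep, an aminopeptidase gene on chromosome 17 (17527723 to 17624489), averaged the 99.5 percentile of YY1 peak length and the 99.8 of both control and shYY1 SMC3. Gsk3b, a kinase gene of Wnt signalling, and Klf13, a zinc finger factor gene, likewise had YY1 and SMC3 in every library. Rbm15 had SMC3 within 1000 bp of an end in 1 control and 1 shYY1 library, and within 2500 bp in 2 and 3. Agpat1 and Rnf5 share the same peaks, as do Gm20783 and LOC108167694 near the end of chromosome 9.

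The third question was how SMC3 differs in cells with the shRNA against YY1. Most control SMC3 genes were also called in shYY1: 2118 (70.5%) had reproducible shYY1 SMC3, and 161 genes had it in shYY1 only. The mean number of peaks differed by -764 between shYY1 and control (exact permutation p = 0.4, n = 3), a difference smaller than the control SD of 1439. YY1 regions with an SMC3 peak made up 43.0% ± 15.4 of all YY1 regions in control and 35.0% ± 3.2 in shYY1 (difference -8.07 percentage points, exact permutation p = 0.4, n = 3). Control libraries gave 51.2, 52.6 and 25.3%, and shYY1 libraries 31.4, 37.5 and 36.0%. Over the libraries of both arms this share rose with the number of peaks, as 89.8 to 96.4% of each SMC3 list lay in YY1 regions. The difference in share thus largely restates the difference in peaks and is not a separate result. Control SMC3 replicate 3 decided these differences: without it they were -1594 peaks and -16.9 points, each with exact permutation p = 0.1, the smallest possible; without control SMC3 replicate 1 or 2 they were -369 or -327 peaks and -3.98 or -3.27 points. Without both libraries whose description names Abcam they were -206 peaks and -2.21 points.

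With all peaks, the concentration of SMC3 on YY1-bound regions differed between the arms by less than the spread of the libraries. That spread followed list length. Over the libraries of both arms the log2 odds ratio fell as the list grew, from 6.86 with 2061 peaks to 5.43 with 4595. A small difference in means therefore does not show that the concentration was unchanged. The log2 odds ratio of an SMC3 peak at H3K4me3 regions with against without YY1 was 5.54, 5.43 and 6.86 in the control libraries (SD 0.80) and 6.31, 5.64 and 6.05 in the shYY1 libraries (SD 0.34), a difference in means of 0.06 (exact permutation p = 0.9, n = 3). Its sign was not stable: it was -0.15 and -0.20 without control SMC3 replicate 1 and 2, 0.51 without control SMC3 replicate 3, -0.10 without shYY1 replicate 1, -0.09 and -0.10 without YY1 replicate 1 and 2, and -0.10 with regions in 3 of 3 libraries. Without both Abcam libraries it was -0.30. With the same number of longest peaks from each library, chosen after the data were seen, it was -0.36, beyond the larger SD of 0.23, and every shYY1 library lay below every control library (exact permutation p = 0.1, the smallest possible). That value rested on 22 to 36 called regions without YY1 per library, with 6.83 the highest shYY1 and 6.84 the lowest control value. Other cuts chosen afterwards gave values above 0: 0.27 with as many random peaks, 0.18 with the 1000 longest and 0.18 with the longer peaks of each list. Random draws keep the make-up of each full list, and the longer peaks leave lists of unequal length. Neither is a like-for-like check of the equal-length value. The 1000 longest rested on 2 to 6 called regions without YY1 per library. SMC3 peaks inside YY1 regions were 92.2% ± 3.6 of each list in control and 93.6% ± 0.90 in shYY1, and peaks near gene ends 67.4% ± 1.2 and 68.6% ± 1.9 (exact permutation p = 0.6 and 0.5, n = 3).

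**Figure D4:**
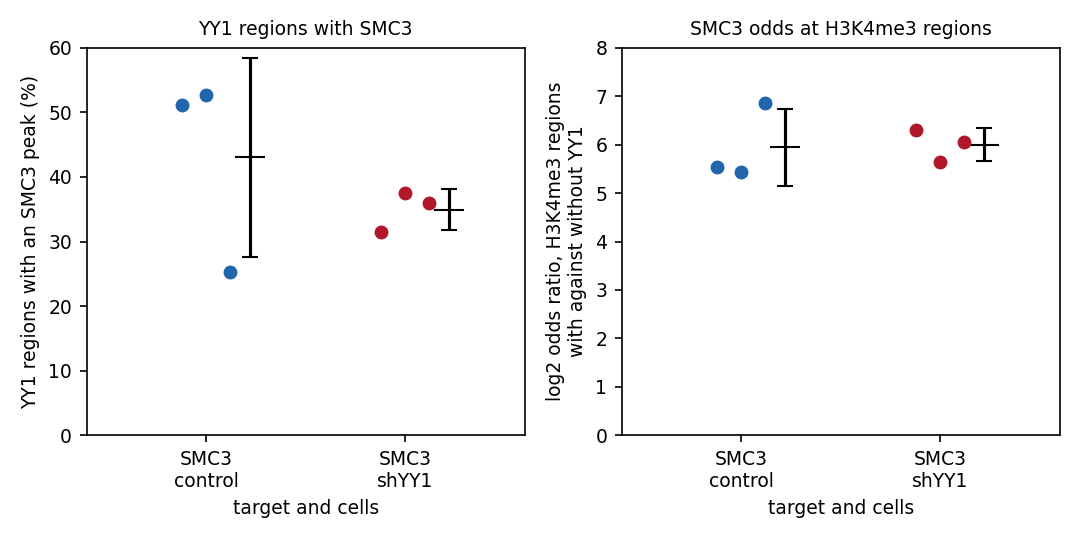
Left, percent of YY1 regions with an SMC3 peak; right, log2 odds ratio of an SMC3 peak at H3K4me3 regions with against without YY1. Points are the 3 libraries of each group and bars the mean with SD; the control range of 25.3 to 52.6% encloses the shYY1 range of 31.4 to 37.5%.

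Over all 6 libraries there were 6175 merged SMC3 regions, of which 1339 were called in every library. In 40 regions every control library and no shYY1 library had a peak, and in 1 region (chromosome 1, 195371648 to 195371963) the reverse held. Of the 40, 36 overlapped a YY1 region, 35 an H3K4me3 region and 25 lay near a gene end. Of all reproducible control SMC3 regions, 94.7% overlapped YY1 and 94.4% H3K4me3, and 67.4% of control SMC3 peaks lay near a gene end. The 40 thus showed no excess of any of these. The control-only count was 439 without control SMC3 replicate 3 and between 67 and 93 without any other SMC3 replicate. The reverse count was between 2 and 26. Leaving out a library also loosened the rule, to every remaining library of 1 arm and none of the other, so higher counts follow by construction. With the same number of longest peaks from each library, a setting chosen after the data were seen, 22 regions were called only in control and 26 only in shYY1. With the longer peaks of each list, also chosen afterwards, the counts were 33 and 2.

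At the level of genes, 1188 had SMC3 at an end in all libraries, 29 only in the 3 control libraries and 1, Slc22a29, only in the 3 shYY1 libraries. The 15 named by rank were Fcho2, Sirt4, Dnttip2, Ovca2, Rchy1, Alyref2, Snd1, Tut4, Nfkbia, Rpl39, Junb, Tuba1a, Nsl1, Tatdn3 and Ptges3. Nfkbia encodes an inhibitor of NF-kappaB and Junb a subunit of the AP-1 factor, and Sirt4 a mitochondrial sirtuin. At Nfkbia and Junb the control peaks lay in separate regions, none called in all 3 control libraries, so neither gene is among the control-only regions. Fcho2, with the longest SMC3 peaks of these (percentile 74.5), had shYY1 SMC3 in 3 libraries once the window was 2500 bp, and Slc22a29 had control SMC3 in 2. Nsl1 and Tatdn3 share a peak (chromosome 1, 191062865 to 191063215). Among regions, Asxl1, Txnip and Stat5a, chosen after their values were seen, were the nearest genes of control-only regions. A control-only region 3561 bp from an end of Kit, also chosen afterwards, had neither YY1 nor H3K4me3. Kit itself had SMC3 at an end in 3 of 3 libraries of both arms, with reproducible YY1 and H3K4me3.

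**Figure D5:**
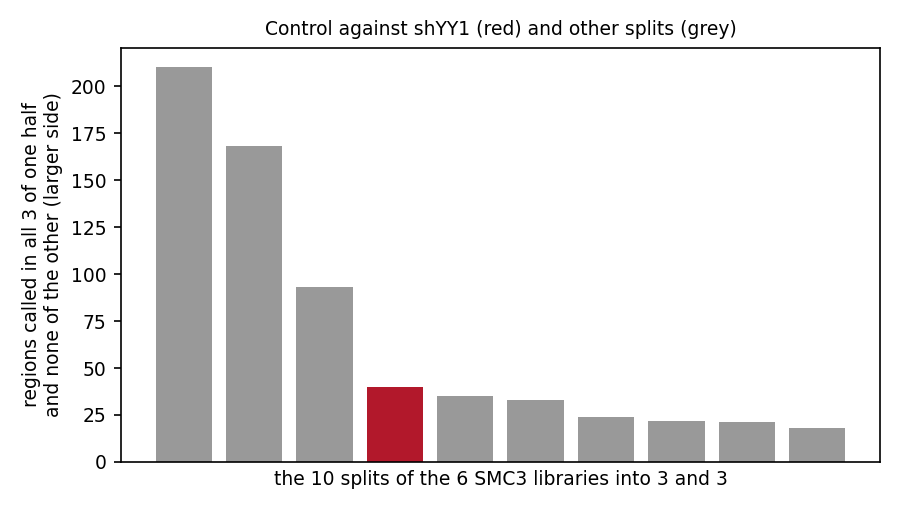
Number of SMC3 regions called in all 3 libraries of 1 side and none of the other (the larger side) for the 10 splits of the 6 SMC3 libraries into 3 and 3. The red bar is control against shYY1 with 40 regions, and the grey bars are the other splits, the highest at 210.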

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

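Tests on lists of equal length, on longer peaks and on only those gene ends that themselves carry H3K4me3, the mitochondrial ribosome comparison, and leaving out a replicate for region counts, gene lists and the fold over random placement of control SMC3 were chosen after the results were seen. With 3 libraries a side no difference between arms could pass 0.05, so an unchanged side of the threshold says nothing of stability. The fold of YY1 over random placement ran from 343 to 563 in the settings run. A fold above 1 follows from the location of both targets in H3K4me3 regions, so this is no sign of stability either. The log2 odds ratio difference (0.06) was below 0 in 8 of 17 alternatives and above 0 in 9: -0.10 with regions in 3 of 3 libraries, -0.30 without both Abcam libraries, -0.36 with equal numbers of longest peaks (exact permutation p = 0.1), but 0.27 with equal numbers of random peaks, 0.18 with the longer peaks of each list and 0.18 with the 1000 longest, where 2 to 6 regions without YY1 were called per library; leaving out 1 replicate gave -0.20 to 0.51. Random draws keep the make-up of each full list and the longer peaks leave lists of unequal length, so neither removes the dependence on list length. The difference in YY1 regions with SMC3 was 0.26 points with random peaks, and leaving out 1 replicate gave -16.9 to -3.27. At gene ends the SMC3 difference was -0.70 points with equal numbers of longest peaks. YY1 minus SMC3 (-1.58) was -6.02 in that setting, in which only the SMC3 lists were cut and the YY1 lists kept all peaks. It was 2.60 with the longer peaks of each list, YY1 included. Regions only in control numbered 22 and only in shYY1 26 with equal numbers of longest peaks, and 33 and 2 with the longer peaks; leaving out 1 replicate gave 67 to 439 and 2 to 26. YY1 lists past the threshold fell from 3 to 0 with regions in 3 of 3 libraries and with the longer peaks, and numbered 0 to 3 leaving out 1 YY1 replicate; the mitochondrial ribosome call was also lost at 2500 bp. The mitochondrial ribosome value below was -1.40 with regions in 3 of 3 libraries (Fisher's exact adjusted p = 0.20; 0.00773 to 0.0425 otherwise). Counts of list members moved by over 1.5 times in 72 of 216 cases, and library counts of named genes in 18 of 282 with the wider window. With the replicate block the differences were -764 peaks (exact p = 0.5), -8.07 points (0.5) and 0.06 (1). With equal group sizes the block cannot move a mean difference, so these match the main values by construction. The block is 1 of the 9 alternatives above 0 for the log2 odds ratio. Same-numbered libraries correlated at -0.0058, 0.033 and -0.028, and pairs with unlike numbers at -0.039 to 0.050. These values show no pairing by number, but as every pair was similarly low they cannot exclude it. Fewer regions pass the 3 of 3 rule by construction. Leaving out 1 library loosens the rule for regions only in 1 arm, so more of them pass. It tightens the rule for reproducible regions of that target, which then need every remaining library. Otherwise the cause was not tested. A stricter peak threshold, top-scoring peaks and motifs were not run. Depth is unknown, which limits every count of peaks.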

Other observations

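The comparison of SMC3 among YY1-bound genes, the lists of equal length or random peaks, the longer peaks and the rule that sets aside the equal-length share were chosen after the main results were seen. The count over splits was planned, but the bound for reading it was written afterwards. The bounds for the equal-length and region-length tests were written before their own values were known.

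Mitochondrial ribosomal protein genes with YY1 had SMC3 less often than other YY1 genes in the main setting. Of 57 such genes, 14 (24.6%) had control SMC3, against 47.9% of other YY1 genes (log2 odds ratio -1.46, Fisher's exact adjusted p = 0.0080, the only one of 36 such tests to pass). With regions in 3 of 3 libraries the log2 odds ratio was -1.40 and the call was lost (Fisher's exact adjusted p = 0.20, with 0.00773 to 0.0425 in the other alternatives). The excess of YY1 itself at these genes was lost without YY1 replicate 1 or 2 (Fisher's exact adjusted p = 0.47 and 0.61), in 3 of 3 libraries (0.47), with the longer peaks (0.76) and at 2500 bp (0.0558). Mrps18b and Mrpl47 had SMC3 in 3 of 3 libraries of both arms, and Mrps36 in 1 control and 2 shYY1 libraries; Mrpl47 shares its peak with the oxidative phosphorylation gene Ndufb5. Cytoplasmic ribosomal protein genes with YY1 had SMC3 at 27 of 60 (45.0%), and 13 of these 27 kept it in shYY1 against 70.8% of other genes (Fisher's exact unadjusted p = 0.017, adjusted p = 0.31). Of 13 progenitor regulators with YY1, 10 had control SMC3 (Fisher's exact unadjusted p = 0.049, adjusted p = 0.44). Genes are not independent replicates.

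Of 1191 regions called in all 9 YY1 and SMC3 libraries, 26 had no H3K4me3 peak. Of these, 6 were on chromosome 9, including 4 between 3001699 and 3020618, and 2 were on chromosome Y. The 4 lay 314613 to 332421 bp from the nearest gene end. As IgG was not analysed, whether such calls depend on the YY1 and SMC3 antibodies was not tested. The median length of the 26 was 382 bp, against 641 bp for all 1191.

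Control SMC3 lay almost entirely within YY1 and H3K4me3 regions, which a background of open promoters common to both antibodies could also give. At equal list length every pair of libraries of 1 target overlapped more than every SMC3 and YY1 pair. The lowest Jaccard index was 0.464 within, the highest 0.417 between, and the mean difference 0.138. That met the bound written against a single common background as the whole cause. However, lists were cut by peak length, which libraries of 1 target share (median 333 bp for YY1, 247 bp for control SMC3), so the test cannot exclude that background. Longer H3K4me3 regions do not account for the overlap, since the log2 odds ratio was at least 5.84 in each of 5 classes of region length. Peak length stood in for peak strength here, and a common background, whole or partial, stays open, as IgG was not analysed here. Binding of cohesin at YY1-bound promoters remains a hypothesis.

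Fewer YY1 regions had SMC3 in shYY1 than in 2 of 3 control libraries. As 89.8 to 96.4% of each full SMC3 list lay in YY1 regions, this share rose with list length over the libraries of both arms. The share alone therefore cannot tell shorter lists from a loss of SMC3 at YY1-bound regions. With equal numbers of longest peaks the difference shrank from -8.07 to -0.26 points. That value met the bound written against list length, as it exceeded the larger SD of 0.193, but over 96.0% of each shortened list lay in YY1 regions, so its length nearly fixed the share and the test decides nothing. A loss at YY1-bound regions stays open: its bound was met by the log2 odds ratio, which differed by -0.36 (larger SD 0.23; highest shYY1 value 6.83, lowest control value 6.84), but on only 22 to 36 called regions without YY1 per library. The difference was above 0 with random peaks (0.27), the 1000 longest (0.18, on 2 to 6 such regions), the longer peaks of each list (0.18) and all peaks (0.06). Random draws keep the make-up of each full list, and the longer peaks and all peaks leave lists of unequal length. Those settings are thus no like-for-like check of the equal-length value. The smallest exact permutation p that 3 libraries a side allow is 0.1.

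The 40 regions with SMC3 in control libraries only were matched or passed in 4 of the 10 splits of the 6 libraries, the real one included. The highest other split gave 210, with control replicates 1 and 2 and shYY1 replicate 2 on 1 side. These were the longest SMC3 lists (4511, 4595 and 3213 peaks). List length was not tested as the cause of the split counts. With 10 splits the share cannot fall under 0.05.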
